A study of Homo sapiens with 3 samples.

How the data were processed

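The series describes RNA-seq and ATAC-seq of NCI-H1975 cells. Values were used from 1 of its samples, the wild-type RNA-seq replicate 2. The 2 wild-type ATAC-seq samples are described by labels only, and no peaks or signal were analysed here. Per the labels' protocols, cells were grown in a standard serum-containing medium, RNA was extracted with Trizol, and a directional RNA library was prepared from 1 ug of total RNA with an NEBNext kit. Whether polyadenylated RNA was selected or ribosomal RNA depleted is not given in the sources used here.

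The deposited file holds raw whole-number read counts per gene, made by the authors and not normalised, with Ensembl gene identifiers and no header. The submitters' processing notes name STAR, featureCounts, Bowtie2 (2.3.3.1), MACS2 (2.1.1.20160309), deepTools (3.3.0) and the human genome build hg19, without saying which was used on which assay. The annotation release, the strand setting and the treatment of reads that map to several places or overlap several genes are not given in the sources used here. Antisense and overlapping genes are uncertain for that reason, and KRT7, for which an antisense gene is annotated, is one of these. Reads that near-identical genes share could have been split or dropped, which would lower the counts of those genes.

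Identifiers were matched without their version to a table of current symbols. Of 60880 rows, 56414 matched, and they held 99.8% of counts. The 41 rows for the Y copy of the pseudoautosomal genes held 0 counts and received no symbol-based use. No row lacked an identifier, so all counts entered the library total. Older histone symbols were resolved through the synonyms of a RefSeq gene table (GRCh38.p14), used for names and gene type only. No coordinates or gene lengths of hg19 were used here, so no positions are given and no length-corrected level was computed.

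Counts were divided by the library total and multiplied to CPM. Each level has an exact (Garwood) 95% Poisson interval, each share an exact (Clopper-Pearson) 95% binomial interval, and each ratio of 2 genes the matching conditional interval. A count of 0 is given as an upper limit of 3 counts. Reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only. With 1 library there is no replicate spread, no p-value was computed and no test between cell states was possible.

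Before the data were examined, 22 gene lists with 284 entries, the detection minimum of 10 counts, the ratios, the alternatives and the rule for named genes were fixed. Of the entries, 277 had a row that matched by name. The 7 without one were PECAM1, RMRP, RPPH1, RN7SL1, RN7SL2, SCARNA2 and HIST1H3B. The rule named the 3 members of each list with the highest counts and up to 3 members under 10 counts, all TFAP2 genes and kinases inhibited by anlotinib, the 10 genes with the highest counts, and BMPR2, HEY1, VEGFA, EGFR and MET. Other list members in the text were added after their counts were seen. A few genes that the rule or the families would name are not reported here. For each list with at least 3 detected members, the median CPM of detected members was placed among the medians of 10000 random lists of the same size drawn from detected genes, as a description and not a test. The random lists were not matched for gene type. Of the 17925 detected genes they were drawn from, 13276 were protein-coding.

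Alternatives were a minimum of 1 count, of 50 counts or of 1 CPM, random thinning of the counts to 50%, and totals without mitochondrial genes or without the 10 genes with the highest counts. The code was tested on simulated Poisson counts for 17925 genes. The 95% intervals held the simulated mean for 95.8% of genes and the simulated ratio for 95.6% of gene pairs. Of 200 simulated lists of 13 genes, 7.5% exceeded the 95th percentile unchanged and 89% exceeded it when raised 8-fold. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.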

Results

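NCI-H1975 is an established human lung adenocarcinoma cell line, and anlotinib is an oral inhibitor of several receptor tyrosine kinases, among them the vascular endothelial growth factor (VEGF) receptors. The study set wild-type NCI-H1975 cells against an anlotinib-resistant derivative by RNA-seq and ATAC-seq, and profiled resistant cells after knockdown of the transcription factor TFAP2A by RNA-seq. Per-gene read counts were examined for 1 RNA-seq library, wild-type replicate 2. The 2 wild-type ATAC-seq samples, the resistant cells and the knockdown cells were not analysed here. No contrast between cell states was therefore made, and the values below describe the transcript levels of the drug-naive parental line in a single library, without a replicate check.

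The library held 25012733 counts over 60880 gene rows. Of these rows, 26725 had at least 1 count and 17925 had at least 10 counts, the minimum used to call a gene detected. Among 19052 protein-coding genes with a row, 13276 were detected. The median detected gene had 360 counts, or 14.4 CPM (counts per 1000000 counts of the library). At this depth 1 count equalled 0.04 CPM, and a count of 0 allowed a level of up to 0.12 CPM. Intervals are 95% Poisson or binomial intervals that cover counting error only. CPM is not corrected for transcript length, so the order of 2 genes by CPM is an order of read numbers and not of molecules.

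TFAP2A, an AP-2 family transcription factor and the gene knocked down in the study, had the highest count of its family in the parental cells. Its 1797 counts (identifier ENSG00000137203.11_3) gave 71.8 CPM (95% interval 68.6 to 75.2), above 82.8% of detected genes. TFAP2C followed with 899 counts and 35.9 CPM (33.6 to 38.4). The ratio of TFAP2A to TFAP2C counts was 2.0 (1.84 to 2.17). TFAP2E had 70 counts, or 2.80 CPM (2.18 to 3.54), and TFAP2B and TFAP2D were both at 0. Of the 5 AP-2 genes, 3 were detected.

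The receptor tyrosine kinases that anlotinib is known to inhibit were mostly low, with the fibroblast growth factor receptors carrying most of their reads. Of 11 such kinases, 6 were detected. FGFR1 was highest at 1195 counts, or 47.8 CPM (45.1 to 50.6), followed by FGFR4 at 510 counts, or 20.4 CPM (18.7 to 22.2), and the ratio of FGFR1 to FGFR4 counts was 2.34 (2.11 to 2.60). FGFR3 had 202 counts, or 8.08 CPM (7.0 to 9.27), and FGFR2 had 12 counts, or 0.48 CPM (0.248 to 0.838). The platelet-derived growth factor receptor PDGFRB had 150 counts, or 6.0 CPM (5.08 to 7.04), whereas PDGFRA was at 0. Among the VEGF receptors, KDR had 35 counts, or 1.40 CPM (0.975 to 1.95), and FLT1 and FLT4 were at 0. KIT had 6 counts and RET had 2 counts, both under the minimum. The median of the 6 detected kinases, 7.04 CPM, lay at the 23.1 percentile of the medians of 10000 random lists of detected genes of the same size. The percentile was 51.5 when lists and random lists took genes with at least 1 count.

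**Figure D1:**
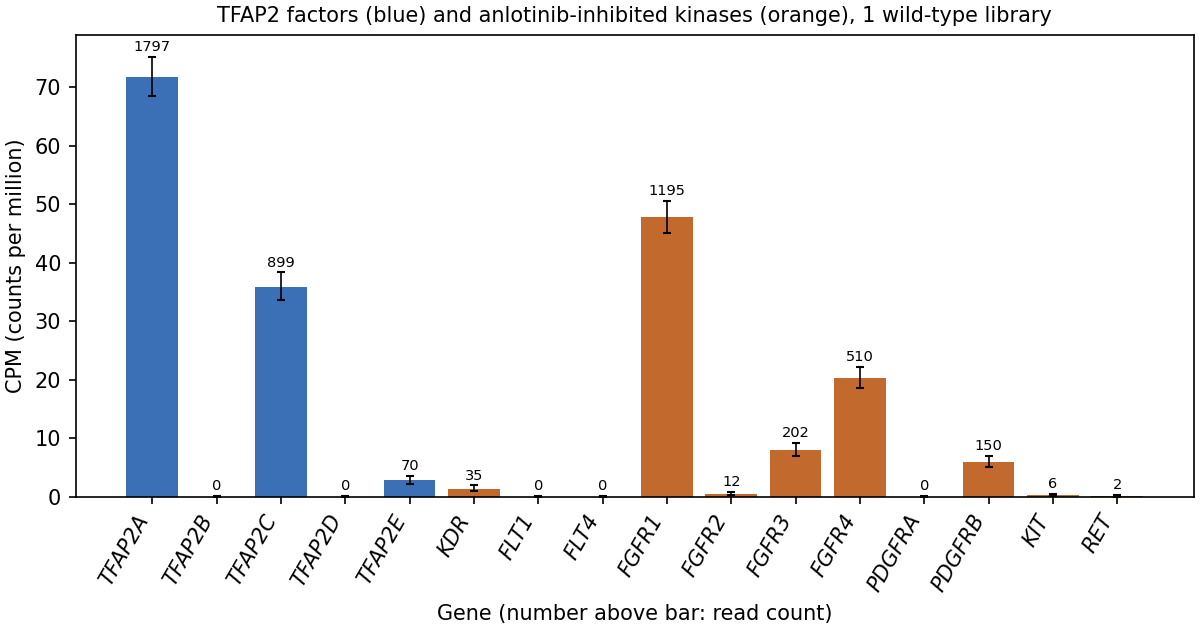
Levels of the 5 TFAP2 genes (blue) and 11 kinases that anlotinib inhibits (orange) in 1 wild-type library. The x axis gives the gene, the y axis CPM on a linear scale from 0, error bars are 95% Poisson intervals (for a count of 0, the bar runs to the 0.12 CPM that such a count allows), and the number above each bar is the read count. TFAP2A has 1797 counts and TFAP2C 899, FGFR1 leads the kinases with 1195, and FLT1, FLT4 and PDGFRA are at 0.

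Ligands of blood vessel growth were read alongside these receptors, since the study's title concerns pro-angiogenic activity. VEGFA, the principal VEGF ligand, had 8849 counts, or 354 CPM (346 to 361), above 97.8% of detected genes. It had 3.87 times (3.69 to 4.05) the counts of the next ligand, the ephrin EFNA1, which had 2288 counts, or 91.5 CPM. The angiopoietin-like protein ANGPTL4 had 1679 counts, or 67.1 CPM, TYMP had 1624 counts and PDGFB had 1555 counts. VEGFB had 1162 counts, PDGFA had 1218 counts and placental growth factor PGF had 383 counts. In all, 18 of 25 listed ligands were detected. VEGFC, HGF, ANGPT1 and ANGPT2 were at 0, VEGFD had 1 count and FGF2 had 2 counts. The neutrophil-attracting CXC chemokines were low, with 136 counts for CXCL2, 44 for CXCL1 and 43 for CXCL8. Detected ligands had a median of 10.4 CPM, at the 29.9 percentile of random lists, or at 70.6 with genes of at least 1 count.

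Of 13 genes known to restrain vessel growth 7 were detected, led by thrombospondin THBS1 at 7473 counts, or 299 CPM (292 to 306). The metalloproteinase inhibitors TIMP2 and TIMP1 had 5302 and 4135 counts, or 212 and 165 CPM, and COL18A1, whose collagen chain contains endostatin, had 3503 counts, or 140 CPM. SEMA3F had 710 counts, VASH1 had 412 and SERPINF1 had 31. THBS2 had 6 counts, and TIMP3, CXCL9, CXCL10 and CXCL11 were at 0. The median of detected members, 140 CPM, lay at the 99.9 percentile of random lists. This percentile and those of other lists leave out members under 10 counts.

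Receptors and mediators of bone morphogenetic protein (BMP) and transforming growth factor beta signalling were broadly expressed, with 19 of 20 detected. The type II BMP receptor BMPR2 had 1312 counts, or 52.5 CPM (49.7 to 55.4). Endoglin (ENG), a co-receptor of this pathway, was highest at 6358 counts, or 254 CPM (248 to 261), followed by SMAD3 at 3384 counts and TGFBR2 at 2630 counts. ID1, a BMP-responsive gene, had 2625 counts, against 794 for ID3 and 129 for ID2. SMAD9 was under the minimum with 7 counts. The median of detected members was 31.7 CPM, at the 92.7 percentile of random lists.

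Notch receptors and Jagged ligands were abundant and Delta-like ligands were scarce. NOTCH3 had 5961 counts, or 238 CPM, NOTCH2 had 5836 counts, or 233 CPM, JAG1 had 5045 counts, or 202 CPM, NOTCH1 had 4228 counts and JAG2 had 2828 counts. NOTCH4, DLL1 and DLL4 had 9, 6 and 9 counts, and DLL3 had 74. Among the target genes, HES1 had 1092 counts, HES4 had 833 counts, HEY1 had 222 counts, or 8.88 CPM (7.75 to 10.1), and HEY2 was at 0. Of 14 members 10 were detected, and their median of 78.4 CPM lay at the 99.5 percentile of random lists.

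The epidermal growth factor receptor EGFR had 8328 counts, or 333 CPM (326 to 340), above 97.6% of detected genes. ERBB2 had 6380 counts, or 255 CPM, the hepatocyte growth factor receptor MET had 5809 counts, or 232 CPM (226 to 238), and ERBB3 had 3634 counts, or 145 CPM. ERBB4 was at 0. The ligands were lower: EREG had 940 counts, TGFA had 749, NRG1 had 633, AREG had 356 and HBEGF had 343, while EGF had 14 and EPGN had 2. Of the 13 receptors and ligands 11 were detected, with a median of 29.9 CPM at the 84.7 percentile of random lists.

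All 13 epithelial markers were detected. The simple-epithelium keratins KRT7, KRT8 and KRT19 had 132533, 65584 and 48349 counts, or 5299, 2622 and 1933 CPM. CLDN4, a tight junction protein, had 20412 counts, and E-cadherin (CDH1) had 10561 counts, or 422 CPM (414 to 430). Their median of 271 CPM exceeded that of every one of the 10000 random lists. Of 11 mesenchymal markers 8 were detected. Vimentin (VIM) had 57711 counts, or 2307 CPM (2288 to 2326), and fibronectin (FN1) had 34838 counts, or 1393 CPM, followed by S100A4 with 970 counts and SNAI1 with 894. CDH2 had 4 counts, and TWIST1 and TWIST2 were at 0. The ratio of CDH1 to VIM counts was 0.183 (0.179 to 0.187). Detected mesenchymal markers had a median of 26.6 CPM, at the 76.2 percentile.

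Of 15 genes of the alveolar and airway lineage 10 were detected. ABCA3, a lipid transporter of surfactant-storing organelles, had 4508 counts, or 180 CPM, the lineage factor NKX2-1 had 2926 counts, or 117 CPM, and FOXA2 had 849 counts, or 33.9 CPM. FOXA1 had 12 counts. The surfactant genes were low, with 62 counts for SFTPB, 1 each for SFTPC and SFTPD, and 11 and 1 for SFTPA2 and SFTPA1, a near-identical pair whose separate values are uncertain. The club cell gene SCGB1A1 was at 0. Detected lineage genes had a median of 9.66 CPM, at the 30.6 percentile, or at 67.3 with genes of at least 1 count. Among 7 squamous markers only TP63, with 418 counts, and SOX2, with 34 counts, were detected, and KRT14, KRT5 and KRT6A had 8, 2 and 0 counts. Among 8 markers of neuroendocrine or small cell lung cancer SYP, with 66 counts, and POU2F3, which marks its tuft-cell-like subtype, with 62 counts, were detected, and NEUROD1 and CHGA were among the 6 at 0.

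All 20 proliferation genes were detected, with a median of 104 CPM above that of every random list. MCM7 had 10385 counts, or 415 CPM, MKI67 had 9320 counts, or 373 CPM, and the topoisomerase TOP2A had 6348 counts, or 254 CPM. All 15 hypoxia-response genes were detected, with a median of 52.4 CPM at the 98.7 percentile. The glycolytic genes ENO1, LDHA and PGK1 led with 83934, 25285 and 18338 counts. CA9, a gene widely used as a hypoxia marker, had 676 counts, or 27.0 CPM, and ALDOA, a glycolytic aldolase whose overlap with other annotated genes could not be checked, had 778 counts. Of 8 drug efflux transporters 6 were detected, with a median of 44.0 CPM at the 88.1 percentile. ABCC3 had 8758 counts, or 350 CPM, ABCC1 had 2914 counts, ABCC5 had 1657 counts and ABCG2 had 302 counts. ABCB1, the multidrug resistance pump, and ABCB4 were at 0.

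Markers of other cell types were read as a measure of what else the RNA could hold. Of 9 endothelial markers with a row 5 were detected: CDH5 had 340 counts, EGFL7 had 58, ROBO4 had 47, ESAM had 18 and VWF had 10. TEK had 1 count, and TIE1, CLDN5 and EMCN were at 0. Of 10 fibroblast markers 4 were detected, with 7847 counts for COL1A1, 4104 for COL1A2, 136 for COL6A3 and 41 for PDGFRL, against 2 for COL3A1 and 0 for DCN and LUM. Of 15 leukocyte and erythroid markers 4 were detected, led by CSF1R with 731 counts, CD14 with 600 and CD79A with 217, while PTPRC had 2, LYZ and CD3E had 1 each, and CD3D and the 3 globin genes were at 0. The medians of detected members were 1.88 CPM (7.74 percentile) for endothelial, 84.8 CPM (95.5 percentile) for fibroblast and 16.3 CPM (47.3 percentile) for leukocyte and erythroid markers. With genes of at least 1 count the percentiles were 31.3, 47.6 and 20.7.

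**Figure D2:**
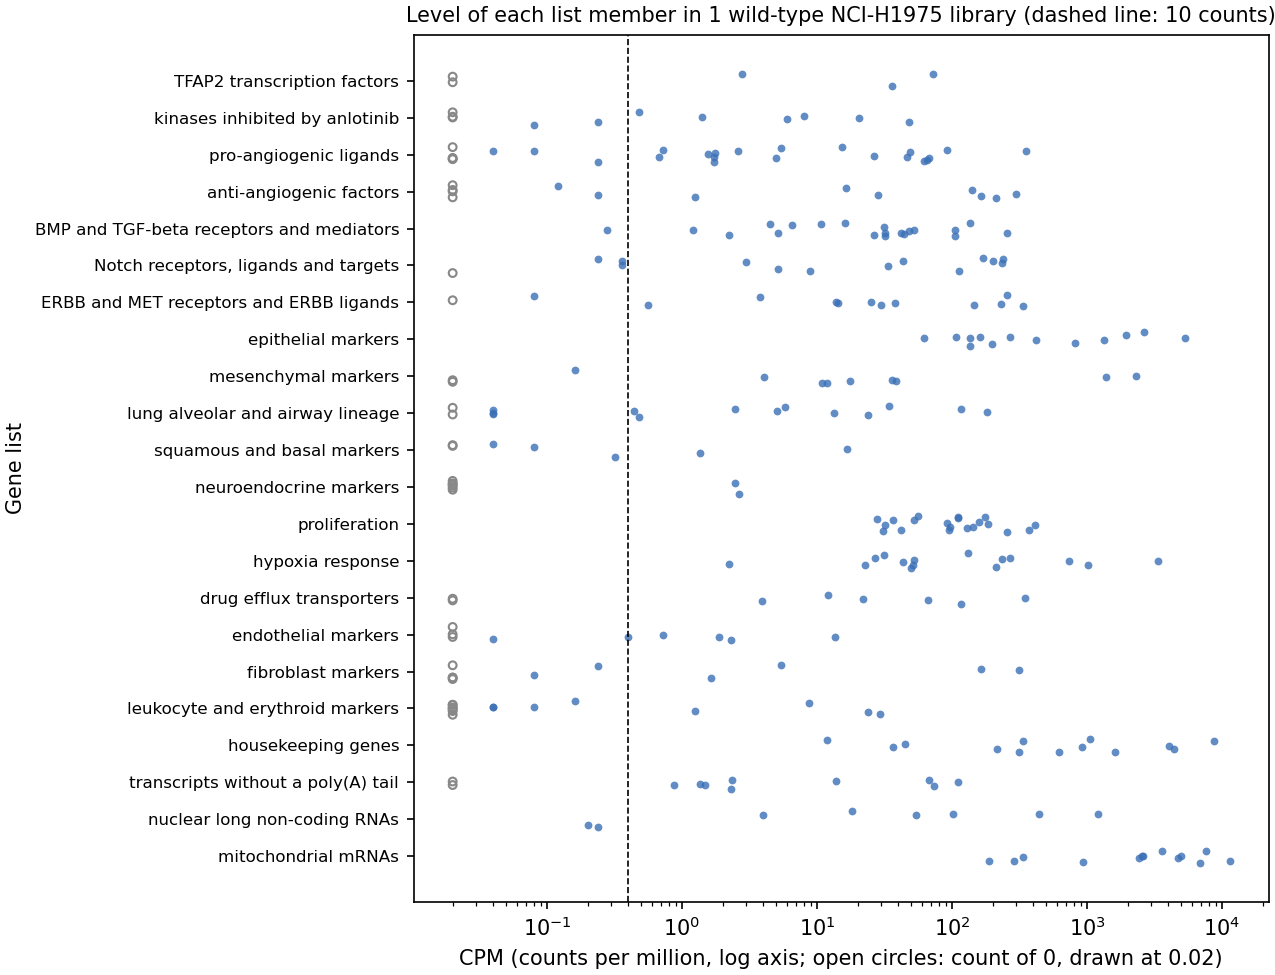
Level of every measured member of the 22 gene lists in 1 wild-type library. Each point is a gene, the x axis is CPM on a log axis, the y axis gives the list, vertical scatter within a list has no meaning, open circles are genes at 0, and the dashed line marks 10 counts. All epithelial and proliferation members lie to the right of the line, while 6 of 8 neuroendocrine members are at 0.

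The 10 genes with the highest counts were MT-CO1 (286021 counts), FLNA (220989), ACTB (216738), MT-ND4 (189069), EEF2 (172556), MT-CO2 (171301), ACTG1 (139053), KRT7 (132533), MT-CO3 (123599) and MT-RNR2 (118716). Together they took 7.08% of counts (7.07 to 7.09). The 37 mitochondrial genes took 5.38% (5.37 to 5.39) and 86 ribosomal protein genes took 5.03% (5.02 to 5.04). The actin genes ACTB and ACTG1 share sequence, so their separate values are uncertain. All 13 housekeeping genes and all 13 mitochondrial mRNAs were detected, with medians of 619 and 2584 CPM above those of every random list. ACTB, EEF1A1 and GAPDH led the former with 216738, 110174 and 100834 counts.

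The 11 listed genes with a row whose transcripts mostly lack a poly(A) tail, of which 9 were detected, took 6865 counts, or 0.0274% (0.0268 to 0.0281). The histone genes H2BC12, H2AC6 and H1-2 were highest with 2787, 1842 and 1679 counts, the first 2 of which can also form polyadenylated transcripts, and the small nuclear RNA RN7SK and the linker histone H1-5 were at 0. Detected members had a median of 2.36 CPM, at the 5.08 percentile, or at 50.2 with genes of at least 1 count. Of 8 nuclear or other long non-coding RNAs 6 were detected, led by MALAT1 with 30185 counts, or 1207 CPM, NEAT1 with 11021 counts and GAS5 with 2531 counts. MEG3 and HOTAIR had 5 and 6 counts. The median of detected members was 77.8 CPM, at the 97.9 percentile.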

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

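The number of detected genes stayed within 1.5 times of its value under each of the 4 alternatives tried, and so did the members detected in 20 of 22 lists at a minimum of 1 count, in 21 at 1 CPM and in 21 after thinning to 50%. The exceptions were squamous markers (5 members at 1 count), leukocyte and erythroid markers (8 at 1 count) and endothelial markers (3 at 1 CPM and 3 after thinning). The 4 ratios stayed inside their intervals after thinning, an alternative chosen after seeing the data. Thinning leaves the expected ratio of 2 genes unchanged, so this result bears on counting error only. With genes of at least 1 count in lists and random lists, 16 of 20 list percentiles moved beyond sampling error of the random draws. They became 88.5 for TFAP2 factors, 51.5 for kinases inhibited by anlotinib, 70.6 for pro-angiogenic ligands, 96.0 for anti-angiogenic factors, 99.7 for BMP and TGF-beta genes, 98.8 for Notch genes and 97.3 for ERBB and MET genes. They became 88.6 for mesenchymal markers, 67.3 for lung lineage genes, 99.96 for hypoxia genes, 96.7 for efflux transporters, 31.3 for endothelial markers, 47.6 for fibroblast markers, 20.7 for leukocyte and erythroid markers, 50.2 for transcripts without a poly(A) tail and 97.1 for nuclear long non-coding RNAs. The new pool holds more genes of low count, and the lists regain their own low members. Leaving mitochondrial genes out of the total raised every other CPM by a factor of 1.06, and leaving out the 10 genes with the highest counts by 1.08. Shares then became 5.32% and 5.41% for ribosomal protein genes and 0.0290% and 0.0295% for transcripts without a poly(A) tail. The mitochondrial share became 1.96% without the 10 genes, and the share of those 10 became 3.73% without mitochondrial genes. Alternatives per kilobase or matched on gene length were not run, because no gene lengths were used. No paired analysis was possible because only 1 library had values.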

Other observations

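Gene families not covered by the lists, chosen after their counts were seen, also had strongly expressed members. Of 26 integrin subunit genes 20 were detected, and ITGA3, a laminin-binding subunit, had 49765 counts, against 13665 for ITGA5 and 12159 for ITGB4. Among 12 laminin chains 10 were detected, with 24303 counts for LAMB3, 15560 for LAMA5, 14580 for LAMB2 and 3762 for LAMA3. P-cadherin (CDH3) had 16817 counts, more than the 10561 of CDH1. The mucins MUC16 and MUC1 had 10116 and 7832 counts, while MUC5AC and MUC2 were under 10 counts.

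The antigen-presentation genes HLA-B and HLA-C had 14012 and 9632 counts, and the class II invariant chain CD74 had 6329 counts with 473 for HLA-DRA and 6 for HLA-DRB1. These HLA genes are polymorphic and resemble each other, so single values are uncertain. Of 19 WNT ligands 7 were detected, and WNT9A and WNT7B held 3696 and 3544 of the family's 7896 counts. None of 37 MAGE-A, MAGE-B, MAGE-C and GAGE genes, which are cancer-testis genes, reached 10 counts in this library, and the family held 4 counts in total.

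The tests below on histone genes and the ratios of listed markers were chosen after those counts were seen. The 3 tests on genes outside the lists were set before the counts of those genes were seen, and the 2 on ribosomal protein genes after the highest ribosomal protein counts had been seen but before the read-through members and the split by pseudogene number were examined. Markers of fibroblasts, leukocytes and endothelial cells were present in part, led by COL1A1, CSF1R and CDH5. Cells of those types would bring their other abundant transcripts. Summed counts of listed markers were first set against COL1A2, CD14 or CDH5. COL3A1, DCN and LUM together had 0.000487 of the COL1A2 count. PTPRC and LYZ had 0.005 of the CD14 count, and VWF, TEK, TIE1, CLDN5 and EMCN had 0.0324 of the CDH5 count. Wider sets, which contain these genes, had 0.0451, 0.0117 and 0.394. A sum can only rise as genes are added, so the rise does not show dependence on the markers chosen. For each type 8 abundant genes outside the lists were then taken. Their median was 0.0348 (bootstrap 95% interval 0.00439 to 0.187) of the COL1A2 count for fibroblasts, 0.0175 (0 to 0.137) of the CD14 count for monocytes or macrophages and 0.00735 (0 to 0.203) of the CDH5 count for endothelial cells. The upper ends of 0.187, 0.137 and 0.203 place each median below the COL1A2, CD14 or CDH5 count it was set against. Absence is not shown, because the intervals cross the limits for absence of 0.01, 0.1 and 0.1 set in advance. Members differ widely. TYROBP, AIF1 and CYBB had 1, 0 and 0 counts but CTSS had 302. MMP2 had 18 but CCDC80 had 768 and COL5A1 had 17047, more than COL1A2 itself. CD34 had 0 but SOX18 and S1PR1 had 69 each. Low counts of COL3A1, DCN, LUM, PTPRC, LYZ and TYROBP weigh against these cells as the main source of the COL1A2 and CD14 counts. The medians set against CD14 and CDH5 also fell short of the presence limit. For fibroblasts the test does not decide, and for no type does it exclude a smaller share of cells. Transcription by the carcinoma cells themselves was not tested.

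Some genes that every cell uses had few counts. RPS10, RPL17 and RPL36A, ribosomal protein genes that also form part of the annotated read-through genes RPS10-NUDT3, RPL17-C18orf32 and RPL36A-HNRNPH2, had 31, 297 and 172 counts. Their median was 0.0158 (bootstrap 95% interval 0.00252 to 0.0282) of the median of 10899 counts in the other 83 ribosomal protein genes, under the predicted 0.1. With only 3 genes, each resampled median is the count of a single gene, so the interval mainly spans their lowest to highest count. Counting that leaves out reads in exons of 2 genes is a candidate explanation. Over all protein-coding genes in read-through symbols the median was 80 counts against 250 in the others, but 24.3% of them against 30.4% were under 10 counts. Ribosomal protein genes with more pseudogenes had 0.916 (0.661 to 1.37) of the median count of those with fewer. The interval lies above the 0.5 predicted for loss of reads to pseudogenes, but reaches below the 0.9 set for no loss. Only genes with more and with fewer pseudogenes were compared, so a loss common to both would not show. Loss of reads to pseudogenes therefore stays open. ALDOA, with 778 counts against 83934 for ENO1, is not part of a named read-through gene, though its overlap with other genes could not be checked.

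The replication-dependent histone genes were low although all 20 proliferation genes were detected. Their median over 60 genes was 32.5 counts, 0.00689 (0.000879 to 0.0131) of the median of 4719 counts in 7 replication-independent histone genes, whose transcripts carry a poly(A) tail. Under-representation of RNA without a poly(A) tail, as selection of polyadenylated RNA would give, predicts that members known to form polyadenylated transcripts too are higher. A set of these, H2AC6, H2BC4, H2BC5, H2BC12 and H2BC21, had 64.7 times (10.25 to 307) the median count of the other 55, but it was chosen when H2BC12 and H2AC6 were known to be highest, so the ratio does not support that explanation, which stays open. Reads dropped between near-identical histone copies stay open too, because the more diverged linker histone genes had 1.10 times (0 to 64.6) the median of the core histone genes, an interval too wide to decide.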
